A study of Mus musculus with 39 samples.

How the data were processed

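Cultured mouse lung fibroblasts from wild-type lungs, depleted of blood, endothelial, epithelial and mural cells with magnetic beads, were given C1q at 3 doses for 4 times, and RNA was sequenced from the 5' ends of transcripts on an Illumina NovaSeq, per the labels' protocols. Reads were processed with cutadapt 2.1.0 and Bowtie2 2.4.2 against GRCm38, per the submitters' processing notes. The counting tool, the gene annotation, the treatment of strand, of reads with several matches and of molecular identifiers are not given in the sources used here. Reads of near-identical genes, and of overlapping or antisense genes, cannot be told apart with certainty in such counts.

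The authors deposited 1 table of raw counts, with 30012 gene names and 39 columns of whole numbers, and all 39 columns were used. The serial numbers in the column names run from 1 to 48 and leave out 13 to 15, 25 to 27 and 37 to 39, which were not analysed here. Column totals ran from 1806106 to 3012518 counts, and 28849 names matched gene symbols of the RefSeq annotation of GRCm38.p6. The table holds 1437 names of the form LOC and number, and no gene of the mitochondrial genome. Columns were matched to samples by the sample title and its serial number in their names, and doses and times come from the labels of those samples. For 9 columns, the third library of 1 µg/ml at 24 h, the 6 of 10 and 100 µg/ml at 24 h and the first 2 of 1 µg/ml at 48 h, the name was spelled differently and the match rests on the number in it. Coordinates are those of the RefSeq annotation of GRCm38.p6, matched by gene symbol.

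Samples were grouped by dose and time, per the labels, with 3 libraries in each of 13 groups. The labels do not say that replicates came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical. Replicate pairs were compared by a chi-square test of their counts over genes with at least 20 counts in the pair. The statistic per degree of freedom ran from 1.31 to 8.48 over the 39 pairs, so no pair looked like a library deposited in duplicate.

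Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) over all 39 libraries in 1 fit with a mean per group. Genes were kept by edgeR's default filter (14419 genes, with 99.4% of the counts), libraries were scaled by TMM, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 20 comparisons were each of the 12 groups against untreated cells, the slope over log10 dose at each of 4 times, 3 comparisons of neighbouring times averaged over doses, and the interaction of dose slope and time. Log2 values per library in components used a prior count of 2. Levels per library are counts scaled to a common library size with the TMM factors (CPM). Of the tested genes, 1896 are predicted genes or unnamed transcripts, which are counted and not named.

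Genes were named by a rule fixed before the data were examined, as were the tests, the gene lists and all alternatives save those said to be added later. The rule took genes with an adjusted p under 0.05 and a mean log2 CPM value of at least 3 whose libraries did not overlap between the groups, which chance gives for 10% of genes with 3 libraries against 3. For times, at least 8 of the 9 later libraries had to lie beyond the median of the earlier ones. It allowed up to 12 of the largest rises and 12 of the largest falls per comparison, and the 12 smallest p-values for the interaction. Members of the fixed lists were named as well. Genes whose call was lost on leaving out 1 library were passed over in the text. The values of some single genes are not reported here.

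Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation. The p-values were adjusted over the 27 lists within each comparison. There were 513 tests, of 27 lists in 19 comparisons. Of these, 284 were called with the preset and 198 with the estimated correlation. The rotation test fry, which does not compare a list with other genes, called 372. Lists with fewer than 5 tested members were not tested. The lists of lymphocyte, erythroid and mitochondrial genes had 0 tested members.

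Alternatives were DESeq2 1.42.0 with its size factors, RLE scaling, no filter, a robust fit, counts thinned to the smallest library total, only the libraries compared, an adjusted p under 0.01, a log2 difference of at least 1, and each library left out in turn. Alternatives added after the data were seen were the columns of 1 header spelling, only the 100 µg/ml library lowest in Tnfrsf26, and counts without the name LOC118568312. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

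The tests were tried on simulated counts with known changes. In a simulated 100 µg/ml at 72 h against untreated comparison, with 14075 genes left by the filter, 32.8%, 65.7% and 90.9% of genes changed 1.5-, 2- and 4-fold were called. Before the filter, 14219 genes were simulated without a change in each comparison, and 3 of them were called. In the slope at 72 h (14089 genes left) 49.3%, 70.1% and 95.5% were called, as were 8 genes simulated without a change. In the 72 against 48 h comparison (14080 genes left) 73.1%, 91% and 95.5% were called, as were 7 genes simulated without a change. In the interaction (14110 genes left) 14.9%, 53.7% and 89.4% were called, as were 6 genes simulated without a change. A raised list was called, and 0 of 26 unchanged lists. In each comparison 67, 67 and 66 genes were simulated with changes of 1.5-, 2- and 4-fold, far fewer than the real comparisons called. A change of 1.5-fold was thus missed for many genes in every comparison simulated. The Benjamini-Hochberg adjustment depends on how many genes change, so the shares called in the real comparisons may be larger.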

Results

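The series profiled mouse lung fibroblasts given C1q, the recognition protein of the classical complement pathway, in culture. The cells came from wild-type C57BL/6 lungs after magnetic depletion of cells carrying CD45, CD31, EpCAM, CD146 or Ter119, which mark blood, endothelial, epithelial and mural cells. They were starved of serum for 24 h and then given C1q at 1, 10 or 100 µg/ml for 2, 24, 48 or 72 h. The 12 dose and time groups and 1 untreated group at 0 h held 3 libraries each, 39 in all. Poly(A) RNA was sequenced from the 5' end, and the values were raw counts per gene, with library totals of 1806106 to 3012518. A total of 14419 genes had enough counts to be tested.

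The first principal component of the 39 libraries held 40.3% of the variance and ran with time, from -54.5 for a library at 2 h to 40.5 for a library at 72 h. The second held 8.02% and parted the 100 µg/ml libraries from those at 1 and 10 µg/ml at each of the 4 times. Among replicates, the third library of 1 µg/ml at 24 h stood apart, with a first component value of 12.5 against -0.511 and 0.555 for the others of its group. The row named LOC118568312 held a mean of 6.75 to 12.8% of the counts per group, and it lay at 7.55 ± 0.416% (SD, n = 3) in untreated cells. Ribosomal protein genes held 10.1 ± 0.345% of the counts in untreated cells and 5.14 ± 0.114% at 100 µg/ml after 72 h (SD, n = 3).

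**Figure D1:**
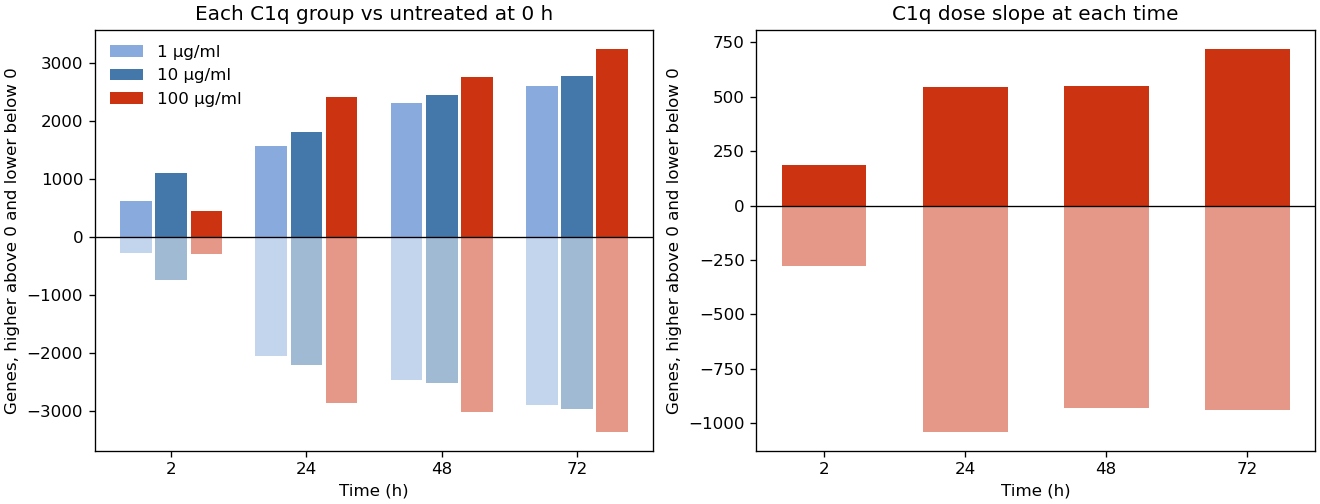
Bars count the genes that were higher (above 0) or lower (below 0), against time in hours, for each C1q group against untreated cells on the left and for the C1q dose slope at each time on the right. Against untreated cells the count went from 744 to 1836 genes at 2 h to 5511 to 6597 genes at 72 h, and the slopes counted 465 genes at 2 h and 1480 to 1658 later.

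Each C1q group was compared with untreated cells to ask what changed after exposure. The untreated cells were taken at 0 h, so time in culture and C1q cannot be parted in these comparisons. All folds are log2 differences ± SE from a fit with 3 libraries per group, and calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. Gene lists were fixed before the data were examined, and unless a sentence says otherwise each list whose count is given also passed a test of the list as a whole (camera, with a preset correlation) in the direction named.

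At 2 h, genes of the immediate early response rose. Among the largest rises at 1 µg/ml were Nr4a3 and Nr4a1, which encode orphan nuclear receptors, at log2 5.35 ± 0.25 and 4.09 ± 0.28. Nr4a3 (GRCm38 chromosome 4, 48045078 to 48086447) rose by 6.07 ± 0.24 at 10 µg/ml and 5.43 ± 0.26 at 100 µg/ml. Ereg, a ligand of the epidermal growth factor receptor, rose by 3.56 ± 0.17 at 1 µg/ml, and Fosl1, a subunit of the AP-1 transcription factor, by 3.10 ± 0.19. Tnfaip6, which encodes a hyaluronan-binding protein, rose by 2.62 ± 0.17, and Dusp5, a phosphatase of ERK kinases, by 2.39 ± 0.23. Of the immediate early genes, 20, 20 and 14 of the 21 rose at 1, 10 and 100 µg/ml (20, 20 and 16 adjusted over the list alone, with 1, 1 and 2 called lower). Fosb rose by 4.16 ± 0.37, 4.70 ± 0.36 and 3.56 ± 0.41 at these doses, whereas Fos was lower at each, at -0.97 ± 0.21, -0.89 ± 0.21 and -1.38 ± 0.23.

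Inflammatory genes rose at 2 h as well. Counts were 10, 12 and 7 of the 19 on the list of inflammatory cytokines and NF-kB genes at 1, 10 and 100 µg/ml (12, 12 and 8 adjusted over the list alone). At 1 µg/ml, Ccl2, a chemokine for monocytes, rose by 2.09 ± 0.13, Ptgs2, the inducible cyclooxygenase, by 2.04 ± 0.14 and Il6 by 1.5 ± 0.28. Of the TGF-beta responsive genes, 7, 9 and 4 of the 14 rose (8, 11 and 6 adjusted over the list alone). Among the falls, Id3, an inhibitor of DNA binding induced by bone morphogenetic proteins, stood at -2.24 ± 0.12, -2.59 ± 0.12 and -1.83 ± 0.11, and Bmp4 at -0.87 ± 0.13 at 1 µg/ml. At 100 µg/ml, Cebpd, a transcription factor gene, stood at -1.72 ± 0.12, Socs3, a feedback inhibitor of cytokine signalling, at -1.46 ± 0.15, and Neat1, a long non-coding RNA of nuclear paraspeckles, at -1.52 ± 0.11.

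In total 887 genes changed at 1 µg/ml after 2 h (617 higher, 270 lower), 1836 at 10 µg/ml (1101 and 735) and 744 at 100 µg/ml (453 and 291). With DESeq2, 487 were higher and 144 lower at 1 µg/ml, 932 and 421 at 10 µg/ml, and 357 and 157 at 100 µg/ml. Leaving out the first untreated library brought the count at 1 µg/ml to 567. At 100 µg/ml, the count was 466 without the second untreated library and 475 without the second library of the dose.

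At 24 h, cell cycle, sterol and contractile genes were lower, and markers of adventitial and alveolar fibroblasts and complement genes higher, than in untreated cells. Clec3b, which encodes tetranectin (chromosome 9, 123150946 to 123157432), rose by 3.44 ± 0.12, 3.30 ± 0.12 and 2.79 ± 0.12 at 1, 10 and 100 µg/ml, and Cilp, a matrix protein gene, by 3.0 ± 0.28, 3.16 ± 0.27 and 2.31 ± 0.30. At 1 µg/ml, Saa3, an acute-phase gene, rose by 2.33 ± 0.30, Dpt, which encodes dermatopontin, by 2.06 ± 0.14 and C3, the central complement component, by 1.72 ± 0.14. Of the complement genes, 13, 13 and 11 of the 18 rose at 1, 10 and 100 µg/ml (14, 13 and 11 adjusted over the list alone, with 1, 1 and 0 called lower). Of the markers of adventitial fibroblasts, 10, 9 and 6 of the 16 rose (10, 10 and 6 adjusted over the list alone, with 0, 0 and 2 called lower), and of those of alveolar fibroblasts, 8, 8 and 6 of the 16 (8, 9 and 6 adjusted over the list alone, with 1, 3 and 1 called lower).

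Among the falls at 24 h were 25, 25 and 25 of the 26 cell cycle genes (25, 25 and 25 adjusted over the list alone) and 21, 21 and 22 of the 22 cholesterol synthesis genes (22, 22 and 22 adjusted over the list alone). Mki67, a marker of dividing cells, stood at -1.39 ± 0.13 at 1 µg/ml and -1.61 ± 0.13 at 100 µg/ml. Tfrc, the transferrin receptor, stood at -2.30 ± 0.27 at 1 µg/ml. Contractile genes of myofibroblasts fell for 15, 15 and 11 of the 18 (15, 17 and 12 adjusted over the list alone, with 1, 1 and 0 called higher), with Acta2, smooth muscle actin, at -0.94 ± 0.13 at 1 µg/ml. The contractile list at 100 µg/ml had an adjusted p of 0.072 with an estimated correlation. Epithelial markers fell for 9, 10 and 10 of the 12 (9, 11 and 10 adjusted over the list alone), and Krt8, a simple epithelial keratin, stood at -1.51 ± 0.13 at 100 µg/ml. Genes of the unfolded protein response fell for 13, 12 and 12 of the 20 (13, 12 and 13 adjusted over the list alone, with 0, 0 and 1 called higher), among them the chaperone Calr at -1.08 ± 0.088 at 100 µg/ml.

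The counts at 24 h were 3637 genes at 1 µg/ml (1575 higher, 2062 lower), 4009 at 10 µg/ml (1802 and 2207) and 5287 at 100 µg/ml (2422 and 2865).

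At 48 h, markers of macrophages were among the rises, in cells from which CD45-positive cells had been depleted. Mrc1, the macrophage mannose receptor, rose by 4.05 ± 0.42 at 1 µg/ml, and C1qa and C1qb, which encode chains of C1q itself, by 2.32 ± 0.20 and 3.13 ± 0.18. Ptprc, which encodes CD45, rose by 1.2 ± 0.32 at 1 µg/ml and stood at 0.52 ± 0.37 at 100 µg/ml, short of the threshold. Lyz2, the lysozyme of myeloid cells, rose by 1.14 ± 0.096 and 1.06 ± 0.097 at these doses. Of the macrophage and other myeloid markers, 15, 15 and 13 of the 18 rose at 1, 10 and 100 µg/ml (16, 15 and 14 adjusted over the list alone, with 0, 0 and 1 called lower). Clec3b rose by 4.23 ± 0.12, 4.32 ± 0.12 and 4.09 ± 0.12, and at 100 µg/ml Saa3 rose by 4.06 ± 0.29, Cxcl13, a chemokine for B cells, by 3.59 ± 0.41 and C3 by 2.49 ± 0.14. Complement genes rose for 16, 16 and 15 of the 18 (16, 16 and 16 adjusted over the list alone, with 0, 1 and 1 called lower), and immediate early genes for 19, 18 and 15 of the 21 (19, 19 and 15 adjusted over the list alone, with 1, 1 and 1 called lower). Matrix proteases and their inhibitors rose for 16, 17 and 12 of the 24 (18, 17 and 14 adjusted over the list alone, with 1, 1 and 4 called lower). At 100 µg/ml that list's adjusted p was 0.071 with an estimated correlation.

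Falls at 48 h took in 25, 25 and 25 of the 26 cell cycle genes (25, 25 and 25 adjusted over the list alone) and 22, 22 and 22 of the 22 cholesterol synthesis genes (22, 22 and 22 adjusted over the list alone). Top2a, a topoisomerase of dividing cells, stood at -2.45 ± 0.12 and -2.87 ± 0.13 at 1 and 100 µg/ml. Epithelial markers fell for 10, 10 and 10 of the 12 (10, 10 and 10 adjusted over the list alone), with Wfdc2, a secreted epithelial protein gene, at -3.54 ± 0.25 at 1 µg/ml. Ribosomal protein genes fell for 57, 44 and 84 of the 88 (66, 51 and 84 adjusted over the list alone, with 0, 2 and 0 called higher). With an estimated correlation, the ribosomal list's adjusted p was 0.4, 0.52 and 0.064 at 1, 10 and 100 µg/ml.

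The counts at 48 h were 4771 genes at 1 µg/ml (2309 higher, 2462 lower), 4969 at 10 µg/ml (2450 and 2519) and 5773 at 100 µg/ml (2754 and 3019).

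At 72 h, markers of macrophages were again among the rises. Mrc1 rose by 5.55 ± 0.34, 5.70 ± 0.33 and 4.29 ± 0.41 at 1, 10 and 100 µg/ml. C1qa rose by 3.64 ± 0.18 and 2.68 ± 0.20 at 1 and 100 µg/ml, and Ptprc by 2.03 ± 0.29 and 1.32 ± 0.32. Of the myeloid list, 17, 17 and 16 of the 18 rose (17, 17 and 16 adjusted over the list alone, with 1, 1 and 1 called lower). Among genes of fibroblasts, Clec3b rose by 4.12 ± 0.12 and 4.41 ± 0.12, Dpt by 3.92 ± 0.13 and 3.26 ± 0.13 and Dcn, the proteoglycan decorin, by 2.09 ± 0.088 and 2.01 ± 0.088. The alveolar fibroblast markers Ces1d and Inmt rose by 2.66 ± 0.14 and 2.14 ± 0.096 at 100 µg/ml. Alveolar markers rose for 10, 10 and 11 of the 16 (10, 10 and 11 adjusted over the list alone, with 2, 2 and 1 called lower) and adventitial markers for 9, 11 and 11 of the 16 (10, 11 and 11 adjusted over the list alone, with 1, 1 and 0 called lower). Of the complement genes, 16, 16 and 15 of the 18 rose (16, 16 and 15 adjusted over the list alone, with 1, 1 and 1 called lower), with C3 at 3.15 ± 0.14 and 3.43 ± 0.14.

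Matrix genes went both ways at 72 h. Fn1, fibronectin, and Eln, elastin, rose by 1.53 ± 0.16 and 1.94 ± 0.12 at 1 µg/ml, whereas Tnc, tenascin C, and Vcan, versican, stood at -1.05 ± 0.14 and -1.40 ± 0.15. Of the 30 matrix genes, 16, 14 and 15 rose and 7, 7 and 8 fell at 1, 10 and 100 µg/ml (16, 14 and 15 adjusted over the list alone for rises, and 7, 8 and 8 adjusted over the list alone for falls). The matrix list's test was upward, and its adjusted p was 0.17, 0.24 and 0.4 with an estimated correlation. At 100 µg/ml, Acta2 and Tagln, contractile genes, stood at -0.68 ± 0.13 and -0.89 ± 0.11. Falls were large for Has2, the main hyaluronan synthase of fibroblasts, at -3.79 ± 0.25 and -4.73 ± 0.29 at 1 and 100 µg/ml. Cell cycle genes fell for 25, 25 and 25 of the 26 (25, 25 and 25 adjusted over the list alone), with Mki67 at -2.66 ± 0.14 and -2.87 ± 0.15. Cholesterol synthesis genes fell for 22, 22 and 22 of the 22 (22, 22 and 22 adjusted over the list alone). The epithelial markers Krt8 and Epcam stood at -2.74 ± 0.15 and -1.91 ± 0.18 at 1 µg/ml, and 10, 10 and 10 of the 12 epithelial markers fell (10, 10 and 10 adjusted over the list alone). Ribosomal protein genes fell for 71, 66 and 88 of the 88 (75, 71 and 88 adjusted over the list alone). With an estimated correlation, the ribosomal list's adjusted p was 0.35 and 0.32 at 1 and 10 µg/ml.

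The counts at 72 h were 5511 genes at 1 µg/ml (2611 higher, 2900 lower), 5748 at 10 µg/ml (2783 and 2965) and 6597 at 100 µg/ml (3240 and 3357).

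The dose slope at each time compared doses among cells of equal time in culture, so time in culture is held fixed without untreated cells. No group was given buffer without C1q. Solutes brought by the C1q stock may rise with dose, and they cannot be parted from C1q in any of these slopes. The slope was fitted over log10 dose, and because the doses are evenly spaced on that scale, its test is the same as that of 100 against 1 µg/ml. The log2 differences of 100 against 1 µg/ml follow, each ± SE with 3 libraries per dose.

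At 2 h, inflammatory genes were lower at 100 than at 1 µg/ml. Has2 differed by -1.69 ± 0.14, Ptgs2 by -1.51 ± 0.13, Ccn1, a matricellular protein gene, by -1.49 ± 0.14 and Cebpd by -1.41 ± 0.12. Neat1 (chromosome 19, 5824708 to 5845480) differed by -1.55 ± 0.10. Lower values were found for 8 of the 19 inflammatory genes (8 adjusted over the list alone), among them the adhesion molecule gene Vcam1 at -0.75 ± 0.10 and the growth factor gene Csf1 at -0.63 ± 0.093. Of the TGF-beta responsive genes, 3 of the 14 were lower (4 adjusted over the list alone). Of the growth factor and receptor genes, 5 of the 24 were lower (8 adjusted over the list alone). Immediate early genes were lower for 6 of the 21 (9 adjusted over the list alone, with 2 called higher) and 1 of those called higher was Atf3, a stress-induced transcription factor gene, at 0.92 ± 0.19. Thbs1, thrombospondin 1, and Tnc were lower, at -1.09 ± 0.10 and -0.59 ± 0.12.

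In all, 465 genes had a dose slope at 2 h (185 higher with dose, 280 lower). The count was 233 without the second library of 1 µg/ml, and 292 and 257 without the first and the third of 100 µg/ml. With only the 9 libraries of this time in the fit, it was 298 (146 higher, 152 lower), without LOC118568312, 206 were higher and 218 lower, and with no filter 218 and 225.

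At 24 h, matrix and complement genes were lower at 100 than at 1 µg/ml. C7, a terminal complement component (chromosome 15, 4987750 to 5063773), differed by -2.18 ± 0.25, Apln, which encodes the peptide apelin, by -2.0 ± 0.26, Col28a1, a collagen gene, by -1.66 ± 0.14 and Penk, preproenkephalin, by -1.5 ± 0.16. Of the matrix genes, 14 of the 30 were lower (16 adjusted over the list alone), including Eln at -1.02 ± 0.11, Fn1 at -0.91 ± 0.16 and Col3a1 at -0.57 ± 0.084. Complement genes were lower for 7 of the 18 (9 adjusted over the list alone), with the protease gene C1s1, whose product binds C1q in the C1 complex, at -0.58 ± 0.087. Matrix proteases and inhibitors were lower for 11 of the 24 (12 adjusted over the list alone, with 1 called higher), with Mmp3 at -0.85 ± 0.085 and the inhibitor Timp1 at -1.13 ± 0.10. Adventitial markers were lower for 6 of the 16 (7 adjusted over the list alone), with the cytokine Il33 at -1.41 ± 0.16 and Igfbp4, an insulin-like growth factor binding protein, at -1.16 ± 0.092. Growth factor and receptor genes went both ways, with 6 of the 24 lower and 2 higher (8 and 5 adjusted over the list alone), and Igf1 stood at -0.75 ± 0.099.

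Cholesterol synthesis genes were lower at 100 µg/ml after 24 h for 13 of the 22 (17 adjusted over the list alone), unfolded protein response genes for 9 of the 20 (12 adjusted over the list alone) and ribosomal protein genes for 76 of the 88 (80 adjusted over the list alone). The chaperones Hsp90b1 and Calr differed by -0.76 ± 0.091 and -0.65 ± 0.087. Contractile genes were higher for 5 of the 18 (7 adjusted over the list alone, with 1 called lower), with Acta2 at 0.57 ± 0.13 and Myl9, a myosin light chain gene, at 0.71 ± 0.12 (list adjusted p = 0.3 with an estimated correlation). Replication-dependent histone genes, whose near-identical copies can share reads, were lower for 15 of the 38 (20 adjusted over the list alone).

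In all, 1582 genes had a dose slope at 24 h, 543 higher and 1039 lower with dose, so that 34.3% were higher. With DESeq2, 263 were higher and 953 lower (21.6% higher). Without the first library of 1 µg/ml the count was 920 and without the second 1041, whereas it was 2203 without the third, the library that stood apart. With only the 9 libraries of this time in the fit it was 1050. The columns at this time carry 2 spellings of their name, and no batch is given in the labels. Within the spelling shared by the third library of 1 µg/ml and all libraries of 10 and 100 µg/ml, 287 genes had a slope (82 higher, 205 lower). The 1 library left at 1 µg/ml, the one that stood apart, is there assumed to vary like the other groups.

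At 48 h, some genes of metal and stress responses were higher at 100 than at 1 µg/ml. Slc30a1, a zinc exporter, differed by 1.76 ± 0.25, and the metallothioneins Mt1 and Mt2, which bind zinc and copper, by 1.24 ± 0.13 and 1.36 ± 0.13. Slc39a10, a zinc importer (chromosome 1, 46807544 to 46925776), was lower, at -1.42 ± 0.11. Ddit3, a transcription factor gene of the integrated stress response, was higher by 1.06 ± 0.11, Trib3, which the same response induces, by 1.23 ± 0.18 and Atf4 by 0.48 ± 0.092. Of the unfolded protein and amino acid response genes, 5 of the 20 were higher (6 adjusted over the list alone, with 1 called lower). The list's mean difference was 0.16 and its test was upward, whereas its median was -0.0054 (above 0 with thinned counts), and its adjusted p was 0.17 with an estimated correlation. Of the oxidative stress and metallothionein genes, 5 of the 16 were higher (5 adjusted over the list alone, with 2 called lower). Lcn2, an iron-carrier-binding acute-phase protein gene, was higher by 2.42 ± 0.36. The alveolar markers Itga8 and Mettl7a1 were higher by 0.90 ± 0.11 and 1.07 ± 0.085.

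Lower at 100 µg/ml after 48 h were Ccn3, a matricellular protein gene, at -2.63 ± 0.36, C7 at -2.24 ± 0.21, Col28a1 at -1.98 ± 0.12 and Spp1, osteopontin, at -1.63 ± 0.12. Myeloid markers were lower for 5 of the 18 (6 adjusted over the list alone), with Mrc1 at -1.70 ± 0.30 and C1qb at -0.70 ± 0.14. Of the cell cycle genes, 15 of the 26 were lower (19 adjusted over the list alone), of the matrix genes 12 of the 30 (13 adjusted over the list alone), of the contractile genes 6 of the 18 (9 adjusted over the list alone) and of the cholesterol synthesis genes 12 of the 22 (14 adjusted over the list alone). Eln stood at -0.82 ± 0.11, Col8a1, a collagen gene, at -0.83 ± 0.13, Mmp3 at -1.01 ± 0.084 and Igf1 at -0.85 ± 0.098. Ribosomal protein genes were lower for 69 of the 88 (81 adjusted over the list alone).

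In all, 1480 genes had a dose slope at 48 h (551 higher, 929 lower), and with DESeq2 343 were higher and 762 lower. Leaving out the first, the second or the third library of 100 µg/ml brought the count to 985, 968 or 957. Within the column spelling shared by the third library of 1 µg/ml and all libraries of 10 and 100 µg/ml, 404 genes had a slope (113 higher, 291 lower), again with 1 library at 1 µg/ml.

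At 72 h the metal genes again differed with dose. Mt1, Mt2 (chromosome 8, 94172618 to 94173567) and Slc30a1 were higher at 100 than at 1 µg/ml by 1.65 ± 0.14, 1.69 ± 0.14 and 1.65 ± 0.30, and Slc39a10 was lower, at -1.57 ± 0.10. Against untreated cells, Mt1 and Mt2 were lower at 1 µg/ml after 72 h, at -1.88 ± 0.14 and -1.43 ± 0.14, and stood at -0.24 ± 0.13 and 0.27 ± 0.13 at 100 µg/ml, short of the threshold. Ddit3 and Trib3 were higher by 1.00 ± 0.11 and 1.14 ± 0.21, Lcn2 by 2.21 ± 0.34 and Srxn1, an antioxidant enzyme gene, by 0.68 ± 0.13. Of the unfolded protein and amino acid response genes, 5 of the 20 were higher (7 adjusted over the list alone, with 1 called lower). That list's adjusted p was 0.21 with an estimated correlation. Oxidative stress and metallothionein genes were higher for 5 of the 16 (5 adjusted over the list alone, with 2 called lower). Igfbp6, an insulin-like growth factor binding protein gene, was higher by 0.89 ± 0.091. Alveolar fibroblast markers were higher for 5 of the 16 (7 adjusted over the list alone), among them Mettl7a1 at 1.23 ± 0.085, Ces1d at 0.54 ± 0.11, Itga8 at 0.50 ± 0.10 and Inmt at 0.45 ± 0.087.

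Contractile, myeloid and sterol genes were lower at 100 µg/ml after 72 h. Contractile genes were lower for 10 of the 18 (11 adjusted over the list alone), with Acta2 at -0.71 ± 0.13, Tagln at -0.91 ± 0.11, Des, desmin, at -0.97 ± 0.16 and Cthrc1, a secreted protein of activated fibroblasts, at -1.19 ± 0.22. Myeloid markers were lower for 9 of the 18 (10 adjusted over the list alone), with C1qa at -0.95 ± 0.13 and Fcer1g, an Fc receptor chain gene, at -0.93 ± 0.13. Spp1 stood at -1.85 ± 0.12. It had 418, 436 and 391 CPM in untreated cells, where C1qa had 4.39, 8.9 and 6.78, so its difference need not come from myeloid cells. Wfdc17 and Ccl6, which macrophages express, stood at -2.35 ± 0.20 and -1.89 ± 0.16. Cholesterol synthesis genes were lower for 16 of the 22 (17 adjusted over the list alone). Ribosomal protein genes were lower for 84 of the 88 (85 adjusted over the list alone). Matrix genes went both ways, with 7 of the 30 lower and 3 higher (7 and 4 adjusted over the list alone). That list's mean difference was -0.14 and its median -0.00015, which lay above 0 with counts thinned to the smallest library total, and its adjusted p was 0.5 with an estimated correlation. Tnc stood at -1.13 ± 0.16, Col8a1 at -1.16 ± 0.12 and Eln (chromosome 5, 134702595 to 134747368) at -0.71 ± 0.11. Grem1, an antagonist of bone morphogenetic proteins, stood at -1.21 ± 0.15 and Igf1 at -0.91 ± 0.099.

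In all, 1658 genes had a dose slope at 72 h (719 higher, 939 lower), so that 43.4% were higher. With DESeq2, 421 were higher and 833 lower (33.6% higher). The count was 1068 without the first library of 1 µg/ml and 1086 without the second of 100 µg/ml.

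**Figure D2:**
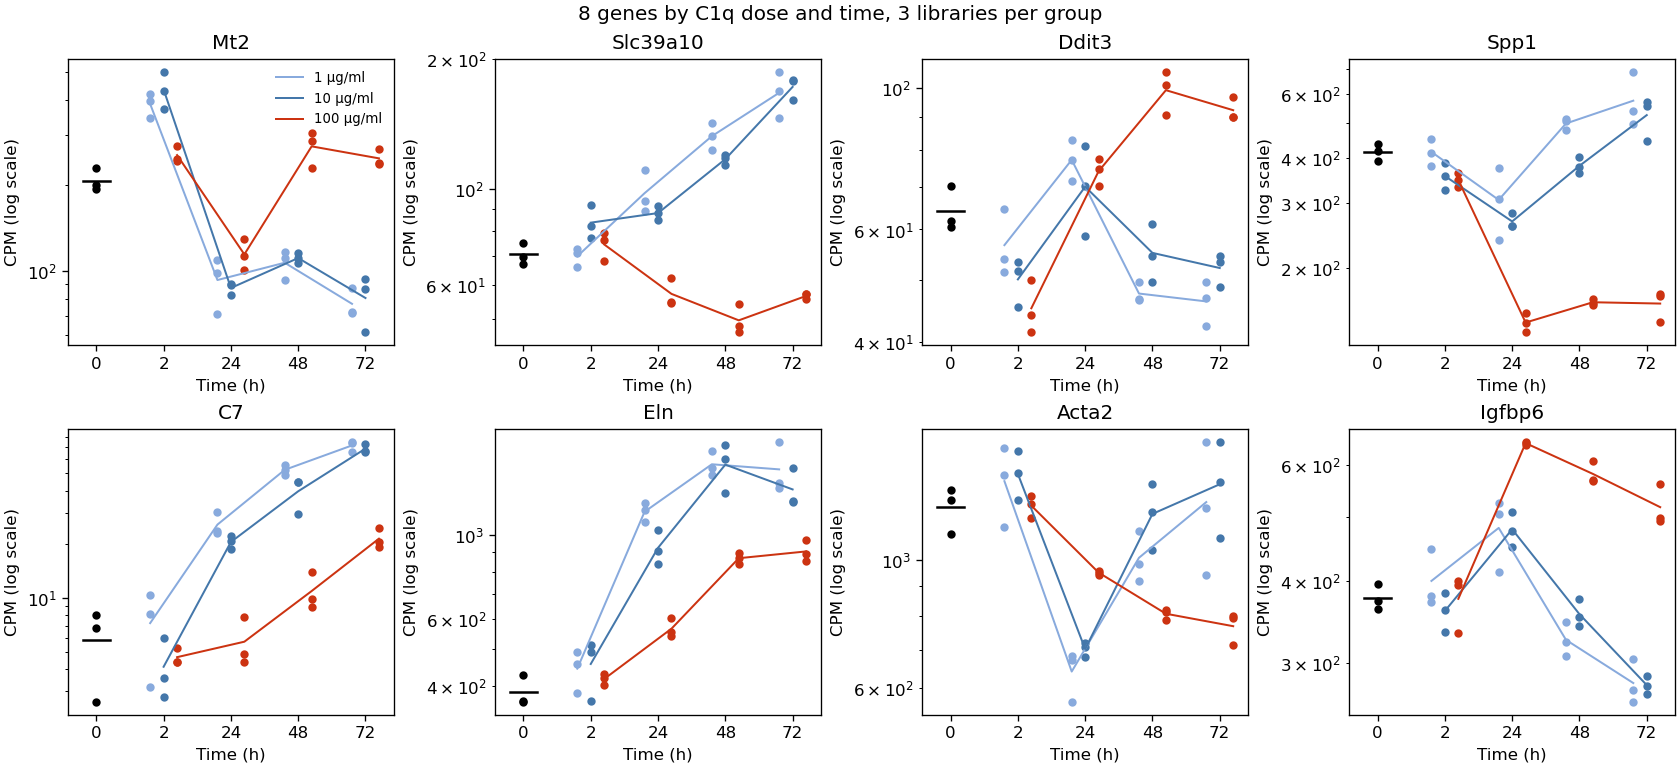
Points are the CPM of each library on a log axis against time in hours, for 8 genes, in untreated cells (black, at 0 h) and at each C1q dose, and lines join the means of 3 libraries. The 100 µg/ml libraries part from the others at 48 and 72 h in Mt2, Slc39a10, Ddit3 and Spp1, where the 100 against 1 µg/ml differences at 72 h were 1.69, -1.57, 1.00 and -1.85.

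The slopes at 24, 48 and 72 h come from separate libraries and shared more genes than independent lists would. At 48 and 72 h, 258 genes were higher with dose at both times, against 27.5 for independent lists, and 495 were lower at both, against 60.5. At 24 and 48 h, the shared genes were 153 higher against 20.7, and 437 lower against 66.9. At all 3 times, 88 genes were higher and 316 lower with dose, and 4 went in mixed directions. The slopes at 2 and 24 h shared 21 higher genes against 6.97 and 47 lower against 20.2, those at 2 and 48 h 30 against 7.07 and 80 against 18, and those at 2 and 72 h 12 against 9.22 and 63 against 18.2. Of the genes lower with dose at 2 h, 17, 9 and 13 were higher with dose at 24, 48 and 72 h. Of those higher at 2 h, 2, 3 and 4 were lower at these times. Numbers for independent lists were not computed for opposite directions, so no reversal is read from these counts.

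Within the slopes, more genes differed between 10 and 100 µg/ml than between 1 and 10 µg/ml. From 10 to 100 µg/ml, 509 genes changed at 2 h (128 higher, 381 lower), 1447 at 24 h (486 and 961), 1344 at 48 h (455 and 889) and 1523 at 72 h (604 and 919). From 1 to 10 µg/ml, edgeR called 121 genes at 2 h (116 higher, 5 lower), 7 at 24 h (6 and 1), 30 at 48 h (30 and 0) and 0 at 72 h. DESeq2 called 120, 10 and 15 genes at 2, 24 and 48 h. At 72 h, 611 genes had an unadjusted p under 0.05, and DESeq2 called 0 genes, with 348 at an unadjusted p under 0.05. At 2 h, the 10 against 1 µg/ml count ran from 45 to 177 as single libraries were left out: it was 77 and 45 without the first and second library of 1 µg/ml, and 67 without the third of 10 µg/ml.

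At 24 h, 168 genes differed between 10 and 1 µg/ml without the third library of 1 µg/ml and 4 without the first of 10 µg/ml. Without the second library of 1 µg/ml, edgeR called 0 genes, with 743 at an unadjusted p under 0.05. At 48 h, the 30 genes rested largely on the first library of 10 µg/ml, which was high in interferon-induced genes. Isg15, a ubiquitin-like protein gene induced by interferon, had 368 CPM in that library and 24.8 and 49.1 in the others of its group, and Ifi44 had 115 against 6.2 and 6.76. Without that library 1 gene differed, without the first, the second or the third of 1 µg/ml 2, 3 or 9, and without the second or the third of 10 µg/ml 73 or 68. Isg15 and Ifi44 were chosen after their values were seen.

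Tnfrsf26, a decoy receptor gene of the tumour necrosis factor receptor superfamily (chromosome 7, 143607685 to 143627845), was high at 100 µg/ml in some libraries of a group and not in others. At 2 h it had 29.8, 1260 and 1360 CPM in the 3 libraries of 100 µg/ml, at 24 h 57.7, 534 and 321, at 48 h 325, 1020 and 938, and at 72 h 531, 272 and 96.7. In untreated cells it had 27.5, 34 and 26.3. Its 100 against 1 µg/ml difference at 48 h was 4.05 ± 0.63, and the gene was singled out after its values were seen. With only the 100 µg/ml library of each time that was lowest in Tnfrsf26, an alternative added after the data were seen, the slopes counted 89, 474 and 528 genes at 2, 24 and 72 h. Against untreated cells the 100 µg/ml counts were then 226 at 2 h, 3326 at 24 h and 4178 at 72 h, in fits where the lone library is assumed to vary like the other groups.

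**Figure D3:**
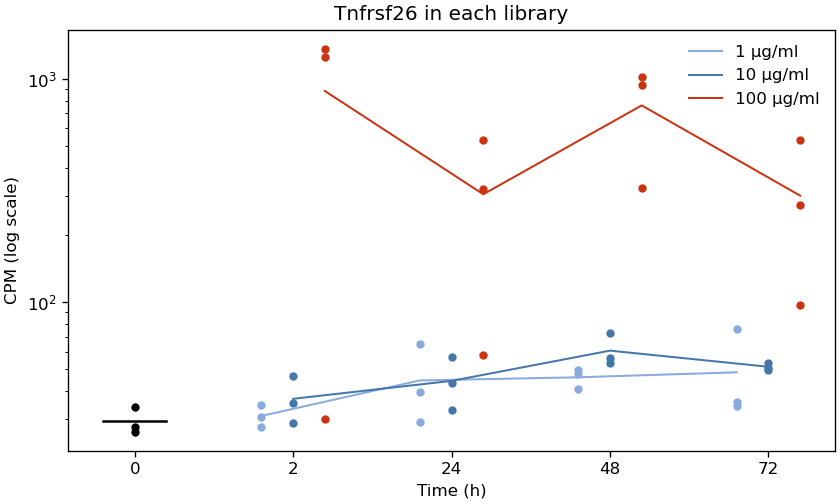
Points are the CPM of Tnfrsf26 in each library on a log axis against time in hours, in untreated cells (black, at 0 h) and at each C1q dose, and lines join the means of 3 libraries. The 100 µg/ml libraries run from 29.8 to 1360, and libraries of one group lie far apart.

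**Figure D4:**
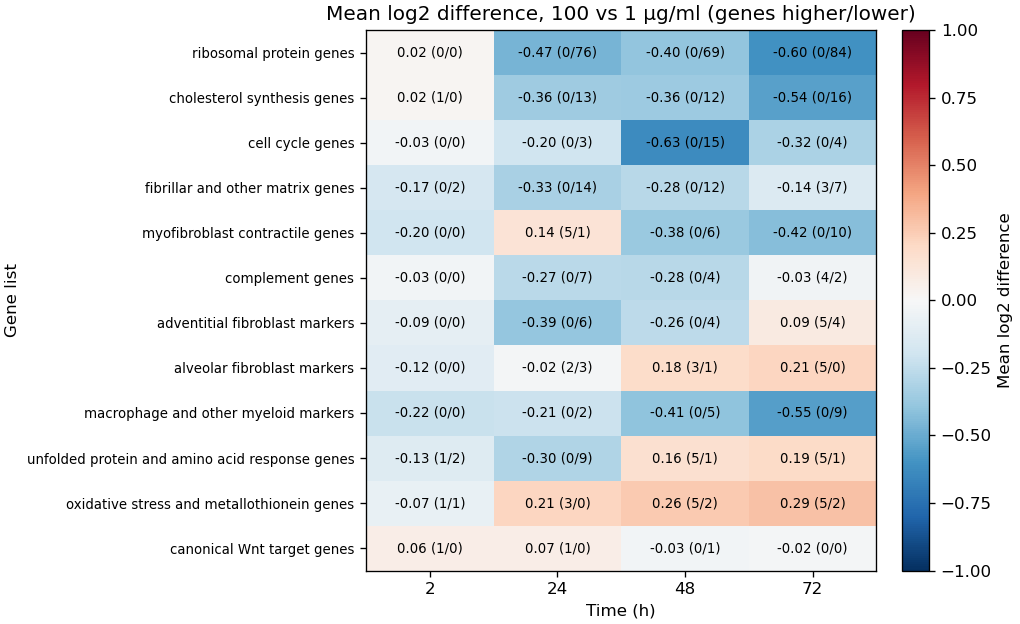
Each cell gives the mean log2 difference of 100 against 1 µg/ml over the tested members of a gene list (named on the left) at a time in hours (along the bottom), with the genes higher and lower in brackets, and colour shows the same mean. Ribosomal protein genes were lower for 76, 69 and 84 genes at 24, 48 and 72 h, and contractile genes went from 5 higher at 24 h to 10 lower at 72 h.

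Neighbouring times were compared over the 3 doses with equal weight, 9 libraries at each time, to ask how treated cells changed with time. Time in culture and time with C1q are the same here. Each time also has its own libraries and the labels give no batch, so differences between collections cannot be parted from time.

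From 2 to 24 h, genes of the immediate early response fell. Nr4a3, Fosl1 and Nr4a1 stood at -4.32 ± 0.12, -4.07 ± 0.13 and -4.03 ± 0.14, and 18 of the 21 immediate early genes (18 adjusted over the list alone, with 1 called higher) were lower. Cell cycle genes fell for 25 of the 26 (25 adjusted over the list alone), with Mki67 at -1.24 ± 0.073, cholesterol synthesis genes for 22 of the 22 (22 adjusted over the list alone), and contractile genes for 17 of the 18 (17 adjusted over the list alone, with 1 called higher), with Acta2 at -0.82 ± 0.073. Clec3b rose by 3.39 ± 0.07, Osr2, a transcription factor gene, by 3.16 ± 0.16 and C3 by 1.53 ± 0.079, and 14 of the 18 complement genes rose (14 adjusted over the list alone, with 1 called lower). In all 8346 genes changed, 4219 higher and 4127 lower.

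From 24 to 48 h the immediate early genes rose again. Ccn1 rose by 2.86 ± 0.082, Atf3 by 2.05 ± 0.16, Nr4a1 by 1.83 ± 0.18, Fos by 1.78 ± 0.092 and Jun, an AP-1 subunit, by 1.11 ± 0.058, and the list counted 18 of the 21 genes higher (19 adjusted over the list alone). Macrophage markers rose too, with Mrc1 at 2.62 ± 0.24, C1qa at 1.30 ± 0.10 and Cd68, a lysosomal protein of macrophages, at 1.24 ± 0.12, and 16 of the 18 myeloid markers were higher (16 adjusted over the list alone). Cdc20, an activator of mitotic exit, stood at -1.69 ± 0.10, and 17 of the 26 cell cycle genes were lower (17 adjusted over the list alone, with 1 called higher). Of the complement genes, 13 of the 18 rose (14 adjusted over the list alone). In all 3589 genes changed, 1846 higher and 1743 lower.

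From 48 to 72 h the immediate early genes fell, 21 of the 21 (21 adjusted over the list alone), with Ccn1 at -3.06 ± 0.085, Nr4a1 at -2.68 ± 0.21, Fos at -2.07 ± 0.097 and Ccn2, a connective tissue growth factor gene, at -1.95 ± 0.068. Of the TGF-beta responsive genes, 7 of the 14 fell (7 adjusted over the list alone, with 1 called higher), with Inhba, an activin subunit, at -1.33 ± 0.067. Txnip, which encodes a thioredoxin-interacting protein, rose by 2.05 ± 0.087 and Neat1 by 1.12 ± 0.053. Myeloid markers rose for 17 of the 18 (17 adjusted over the list alone, with 1 called lower), with Mrc1 at 1.70 ± 0.13, and complement genes for 12 of the 18 (12 adjusted over the list alone). In all 2402 genes changed, 1209 higher and 1193 lower.

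The dose slope was then compared across the 4 times, to ask which genes answered to dose differently with time. Neat1 was lower at 100 than at 1 µg/ml at 2 and 24 h, at -1.55 ± 0.10 and -1.18 ± 0.091, and stood at 0.02 ± 0.094 and 0.18 ± 0.088 at 48 and 72 h. Mt2 ran the other way, at -0.59 ± 0.12 at 2 h and 1.69 ± 0.14 at 72 h. Atf5, a transcription factor gene of the amino acid response, stood at 0.14 ± 0.079 at 2 h, 0.98 ± 0.081 at 48 h and 1.29 ± 0.081 at 72 h. Thbd, which encodes thrombomodulin, stood at -0.64 ± 0.094 at 2 h and 1.00 ± 0.10 at 72 h. Of the lists, the interaction was called for 68 of the 88 ribosomal protein genes (83 adjusted over the list alone), 14 of the 24 growth factor and receptor genes (17), 11 of the 18 contractile genes (13), 11 of the 22 cholesterol synthesis genes (13) and 11 of the 20 unfolded protein and amino acid response genes (12).

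In all, edgeR's quasi-likelihood test called an interaction of dose slope and time in 978 genes, and no test of a list as a whole was run for it. Without the third library of 1 µg/ml at 24 h the count was 1473.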

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

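The tests of an oxidative stress response, a glucocorticoid response, the C1q stock, both tests on Tnfrsf26 and the test of the share of myeloid cells were chosen only after the result was seen, whereas those of scaling and depth and of other splits of the libraries were fixed earlier.

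The effect of dose differed between times in 978 genes, by edgeR's test of the interaction. The 12 genes with the smallest adjusted p are given with their differences of 100 against 1 µg/ml at 2, 24, 48 and 72 h. Neat1 (adjusted p = 4.3e-14) stood at -1.55, -1.18, 0.02 and 0.18, Atf5 (1.1e-12) at 0.14, -0.04, 0.98 and 1.29, and Mt2 (1.1e-12) at -0.59, 0.30, 1.36 and 1.69. Thbd (1.5e-11) stood at -0.64, 0.51, 0.67 and 1.00, Mt1 (2.3e-11) at -0.35, 0.08, 1.24 and 1.65, and Slc39a10 (2.3e-11) at 0.09, -0.78, -1.42 and -1.57. Mmp8 (8.1e-10), a collagenase gene, stood at -0.11, -1.37, -1.26 and -1.03, Spp1 (2.1e-09) at -0.25, -1.12, -1.63 and -1.85, and Ddit3 (2.1e-09) at -0.32, -0.06, 1.06 and 1.00. Gfpt2 (2.2e-09), of the hexosamine pathway, stood at -0.75, 0.38, 0.45 and 0.37, Cebpd (4e-09) at -1.41, -0.06, -0.27 and 0.20, and Igfbp4 (5.5e-09) at 0.13, -1.16, -0.78 and -0.34. In 40 splits of the libraries the real one counted 924 genes and the highest other 337, so 1 of 40 was as large. The splits moved doses within each time and so removed every effect of dose. A chance split of these libraries is thus excluded for an effect of dose at some time. Whether that effect differed between times cannot be decided by these splits.

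The first pattern is the metal genes, with Mt1, Mt2 and Slc30a1 higher and Slc39a10 lower at 100 than at 1 µg/ml at 48 and 72 h, where Mt1 fell from 347, 399 and 322 CPM in untreated cells to 94.1, 103 and 91.6 at 1 µg/ml after 72 h, with 291, 297 and 316 at 100 µg/ml, whereas Slc39a10 rose from 69.4, 67 and 75 to 146, 169 and 187, with 56.9, 56.9 and 55.5 at 100 µg/ml. Scaling or depth is argued against, since 32 of 32 calls of these 4 genes held with their sign under 4 such settings, the smallest difference being 1.18. Over 9 oxidative stress genes at 72 h the median difference was 0.156 (SD 0.348, 3 called higher and 0 lower, by edgeR), beside 1.65 for Mt1. Over 4 glucocorticoid genes the median was 0.227 (SD 0.341), with Tsc22d3 at 0.399, Zbtb16 at 0.303, Per1 at 0.151 and Fkbp5 at -0.366. Of these, edgeR called 0, and 2 had an unadjusted p under 0.05, counted in either direction. These values argue against either response as the whole cause only if it raises its genes as much as Mt1. How strongly each gene answers was not measured, so a response that raises Mt1 more than the other genes is left open. More available zinc, or solutes brought by the C1q stock, may account for these differences as C1q itself may, and these cannot be told apart because 0 groups were given buffer without C1q.

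The second pattern is Tnfrsf26 and genes that moved with it at 100 µg/ml, of which some were also higher at lower doses. From 24 h on this held for 2810407A14Rik in all but 1 library, with 269, 197 and 818 CPM at 1 µg/ml after 24 h, 606, 519 and 613 after 48 h, 380, 364 and 832 after 72 h and 462 to 766 at 10 µg/ml, against 209, 241 and 228 in untreated cells. At 1 µg/ml after 48 h, Tbata had 36.6, 42.5 and 49.3 CPM, against 16.3, 27.2 and 19.9 in untreated cells. Tnfrsf26 itself had 41, 47.4 and 49.7, against 27.5, 34 and 26.3. Amt overlapped, at 8.41, 10.4 and 9.78 against 6.38, 11 and 6.78. For Tnfrsf26, ratios of highest to lowest library of 45.7 at 2 h and 9.25 at 24 h, the values that singled the gene out, argue against a response shared by all libraries of 100 µg/ml at those times. The ratios of 3.15 at 48 h and 5.49 at 72 h lie nearer the 2.24 that was the largest in the other 9 groups, and leave it open there. One outside source of reads with a fixed mix predicts constant shares: of 11 genes picked at 2 h, 8 kept their share of the Tnfrsf26 excess within 1.5-fold at 48 h and 3 did not, 2 of them by more than 2 SE of counting error and 0 by more than 2 SE with the spread between libraries, a spread added after the shares had been seen. An outside source with a fixed or a varying mix, or a response in some cultures only, may account for the set, and these cannot be told apart.

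The third pattern is the lower level of myeloid genes at 100 than at 1 µg/ml at 72 h, in cells depleted by CD45, a gate that should remove macrophages. Over 12 myeloid genes, which no other fixed list held and which all had counts in each untreated library, the median difference was -0.647, with 11 below 0 and 7 called lower by edgeR. Scaling or depth is argued against, since the median nearest 0 under 4 such settings was -0.615. A lower share alone predicts 1 common difference if the genes come from 1 uniform kind of myeloid cell and from no other cells. That case is argued against by Cochran's Q over the n = 12 genes, which are not independent (34.7, chi-square p = 0.00028), with Mrc1 at -1.26 and Adgre1 at 0.15. Q cannot argue against a lower share of only some kinds of myeloid cell, which can also give unequal differences. A lower share of some of these cells, or of all of them together with a response within them, may remain. At 72 h, C1qa had 81.5 ± 8.34 CPM at 1 µg/ml and 42.2 ± 3.87 at 100 µg/ml (SD of the 3 libraries). Lyz2, outside the 12 genes, had 678 ± 59.4 and 668 ± 72.2 CPM. In untreated cells Lyz2 had 200 ± 12.6 CPM and C1qa 6.69 ± 2.26 (SD of the 3 libraries). The level of Lyz2 thus need not come from myeloid cells alone, and it cannot decide on their share.

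For the slopes, 100 splits of the 9 libraries of a time were drawn in fits of these libraries. At 2 h the real split counted 298 genes and the highest other 179, and at 24 h 1050 and 923, so 1 of 100 was as large. At 48 h it counted 1552 and the highest other 1654, and at 72 h 1745 and 1810, so 2 of 100 were as large, and in that other split the 3 libraries of 100 µg/ml also stayed together. Of 60 splits per pair of times, 1 was as large at each: 7916 genes and 32 for 24 against 2 h, 3339 and 1860 for 48 against 24 h, and 2547 and 50 for 72 against 48 h. A chance split of these libraries can be excluded for these 7 comparisons. Chance differences between single cultures cannot, because the replicates may be technical.

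Each group of 3 against the 3 untreated libraries allows 10 splits, too few for a share under 0.05. The real splits at 1, 10 and 100 µg/ml counted 927, 1747 and 997 genes at 2 h, 2445, 4541 and 5519 at 24 h, 5140, 4740 and 6085 at 48 h, and 5186, 6162 and 6727 at 72 h. The highest other split counted 0 genes in each, with edgeR, and the real one was the 1 split as large.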

How the results depend on the processing

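The alternatives with 1 header spelling, with only the 100 µg/ml library lowest in Tnfrsf26 and without LOC118568312 were chosen after the data were seen. Every count of the 20 comparisons stayed within 1.5 times under DESeq2, RLE scaling, no filter, a robust fit, thinned counts and without LOC118568312. With an adjusted p under 0.01 the counts were 483, 1013 and 378 at 2 h and 2243 and 2613 at 24 h (1 and 10 µg/ml) against untreated, 218, 824, 731 and 854 for the slopes at 2, 24, 48 and 72 h, 2296 for 48 against 24 h, 1355 for 72 against 48 h and 481 for the interaction. With a log2 difference of at least 1, fewer genes pass by construction: 182, 393 and 200 at 2 h, 830, 1016 and 1320 at 24 h, 1449, 1617 and 1769 at 48 h, 1764, 1861 and 2295 at 72 h, 17, 12, 29 and 23 for the slopes (per 10-fold dose), and 1204, 289 and 181 for times. With only the libraries compared, the slopes at 2 and 24 h counted 298 and 1050. Coded as 10 against 1 µg/ml, edgeR called 121, 7, 30 and 0 genes at 2, 24, 48 and 72 h (611 at 72 h with an unadjusted p under 0.05). DESeq2 called 120, 10, 15 and 0. Within 1 header spelling, the slopes at 24 and 48 h counted 287 and 404 genes, with fewer libraries. With only the 100 µg/ml library lowest in Tnfrsf26, counts were 226, 3326 and 4178 at 2, 24 and 72 h against untreated and 89, 474 and 528 for the slopes at 2, 24 and 72 h.

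Leaving out 1 library gave 567 to 724, 1334 to 1510 and 466 to 558 genes at 2 h against untreated (1, 10 and 100 µg/ml), 2761 to 3682, 3217 to 3502 and 4440 to 4709 at 24 h, 4083 to 4293, 4252 to 4442 and 4993 to 5122 at 48 h, and 4520 to 5173, 4977 to 5122 and 5675 to 5975 at 72 h. The slopes ran from 233 to 483, 920 to 2203, 957 to 1544 and 1068 to 1632, the times from 8078 to 8315, 3270 to 3909 and 2027 to 2376, and the interaction from 707 to 1473. Of 636 named genes by comparison, 20 lost the call when some library was left out and 0 changed sign. The list tests went from 284 calls to 198 with an estimated correlation and to 372 with fry. The largest shift of the median of all genes by scaling was 0.029. No paired analysis was possible because the replicate numbers were given in accession order. Where no construction is named, the cause was not tested. Pseudocount alternatives apply to normalized values and were not run.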

Other observations

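Endothelial and mesothelial markers were also lower with dose. Of 14 endothelial markers, 3, 4 and 4 were lower at 24, 48 and 72 h (3, 5 and 4 adjusted over the list alone), with Cldn5, a tight junction gene, at -0.75 ± 0.17 and Cd93, a receptor described to bind C1q, at -1.15 ± 0.20 for 100 against 1 µg/ml at 72 h (list adjusted p = 0.024, 0.023 and 0.064 with an estimated correlation). Of 12 mesothelial markers, 4 and 5 were lower at 48 and 72 h (7 and 5 adjusted over the list alone), with Upk3b at -0.69 ± 0.11 at 48 h and Gpm6a at -0.72 ± 0.12 at 72 h (list adjusted p = 0.046 and 0.064 with an estimated correlation). Of 16 p53 and senescence genes, 3 were higher and 1 lower at 48 h (5 and 2 adjusted over the list alone), with Phlda3 at 0.66 ± 0.10 and Igfbp3 at -1.15 ± 0.18.

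Of 12 described C1q-binding proteins, 6 were higher and 4 lower at 100 µg/ml after 72 h than in untreated cells, and the list was not called by camera (adjusted p = 0.77). Cd93 rose by 1.2 ± 0.27 and Lrp1 by 0.92 ± 0.17, whereas C1qbp, the receptor for the globular heads, stood at -1.11 ± 0.14 and the integrin gene Itga2 at -1.99 ± 0.20. Genes of hypoxia and glycolysis were lower at 24 h for 11 and 13 of 22 at 1 and 100 µg/ml (14 and 14 adjusted over the list alone), with Eno1, enolase, at -0.95 ± 0.12 and -1.35 ± 0.12 and Hk2, hexokinase, at -2.07 ± 0.26 at 100 µg/ml. Canonical Wnt targets were higher for 4 of 13 at 10 µg/ml after 2 h (4 adjusted over the list alone, with 0 called lower), with Myc at 2.06 ± 0.20 and Ccn4 at 0.97 ± 0.095. In that comparison 12.7% of all tested genes changed. At 10 µg/ml after 72 h against untreated cells, the Wnt list's median was 0.00043, and -0.091 with thinned counts. The Wnt list was not called in the slopes at 2, 24, 48 and 72 h by camera (adjusted p = 0.69, 0.62, 0.9 and 0.87).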
